A study of Mus musculus with 6 samples.

How the data were processed

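The data were peak lists of 6 ATAC-seq libraries from mouse Tregs, 3 WT and 3 Il33 KO, grouped by the genotype in the labels and named by the replicate numbers of the titles (2, 4 and 6 for WT, and 1, 2 and 4 for KO). The labels name in-house Tn5, MinElute purification and amplification with the NEBNext High-Fidelity mix. Per the submitters' processing notes, the genome build was mm10 and the tools included Bowtie2 2.3.1 and Picard 1.88. Peaks were called on each library alone, with no control library, with MACS 2.1.1.20160309 per the file headers. Per the file headers, the calls used a q-value of 0.05, no fragment model, tags shifted by -100 bp and extended to 200 bp, which centres each tag on the Tn5 cut, single-end mode, 1 tag kept per position, a local background window of 10000 bp and an effective genome size of 1.87e+09. Whether tags were also moved by the offset of Tn5 insertion, or mitochondrial tags removed, is not given in the sources used here.

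The deposited pileup is a signal, the coverage by extended tags at the summit of a peak, not scaled to library depth. The deposited −log10 p-value and −log10 q-value give the significance of that height over the local background. For 100% of peaks the p-value equalled the Poisson tail of the height over the background within 0.01 on the log10 scale plus 0.1% of the value. The deposited fold enrichment is the ratio of height to local background, both plus 1. Because a fixed q-value was applied to libraries of different depth, a deeper library can call weaker sites, which changes the number of peaks and the presence calls derived from them. Heights and folds of single peaks were therefore not tested between genotypes, and only their medians per library were. Heights and backgrounds scaled between libraries were used only to predict losses by depth, and the stricter threshold set 1 significance for all lists. Depths were the tags kept after filtering, per the file headers, of 4.72 to 15.2 M (mega) tags per library. A region absent from a list is one that was not called at that depth, which does not show that it was closed.

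Peaks of all 6 lists were merged where they overlapped by at least 1 bp, giving 64817 regions with a median width of 518 bp, and a library had a region where one of its peaks lay in it. Regions called in all 3 libraries of one genotype and none of the other were called WT-only or KO-only. Within-list percentiles rank each peak by the significance of its own list, 100 being the strongest. Genes came from a table of NCBI RefSeq gene spans on GRCm38.p6, the assembly behind mm10. The share of peaks within 1 kb of a gene end was 23.9% to 31.3% per library and 7.31% to 7.60% after all peaks were moved by 100 kb. A region belonged to a protein-coding gene if it overlapped the gene or 10 kb on either side, and 16246 of 21887 such genes had a peak in some library. The table gives neither strand nor exons, so shares were taken around both gene ends in place of transcription start sites and over whole gene bodies in place of exons and introns. Nearest genes were likewise found by gene ends. Sequence motifs were not analysed here. Of the 244 gene symbols in the 15 lists, 243 were matched.

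Groups were compared by two-sided exact permutation tests of the difference of means over all 20 assignments of the libraries, whose smallest p is 0.1. Similarity was the number of shared bases over the number of bases in either list, compared over the 10 splits into 3 and 3. Lists were tested with Fisher's exact test against regions called in exactly 3 libraries in another pattern, with Benjamini-Hochberg adjustment over 15 lists and 2 directions. The lists cover Treg core, effector or tissue Treg, Th1, Th2, Th17, Tfh, naive and homing, NF-kB, activation, interferon response and housekeeping genes, and markers of B, CD8 T and NK, myeloid and melanoma cells. The main tests, the lists and the naming rule were fixed before the data were examined, while the strength-matched expected counts and the other splits of region counts were added later. The text names genes from a set of 17 chosen in advance, the 8 strongest WT-only and KO-only regions near a gene, and up to 4 genes per list with a group-only region. Alternatives were a stricter threshold, equal-length lists, 50% coverage of a region, windows of 200 bp around peak centres, gene ends only, the nearest gene end within 100 kb, 5 kb around gene ends, autosomes without chromosome 19, leaving out each library, and pairs by shared replicate number.

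The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9. The steps were tested on simulated data made from the 29419 regions called in all 6 libraries, in 5 simulations, in which each planted region was missed by a library with a chance of 10% and part of the other regions was called at a lower rate. For the WT-only comparison 72.0% of 200 planted regions were recovered, where these misses allow 72.9%, and for the KO-only comparison 74.0% of 100. A list planted in 20 of the 200 WT-only regions was called in 5 of 5 simulations, and no list was called with nothing planted. Outside the planted regions the simulated libraries of both genotypes had the same call rates, so the difference in depth was not simulated. The planted list was also far more frequent than any list in the full data (at most 14 of 3022 WT-only regions). Recovery of such smaller counts was not tested. A strength-matched odds ratio of 3, planted at the 956 chromosome X regions among 43512, was recovered as 3.05 on average, and one of 1 as 0.963.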

Results

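Accessible chromatin was mapped by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in regulatory T cells (Tregs) from mice carrying B16.F10 melanoma, a transplantable tumour line of C57BL/6 origin. Tregs were sorted as CD4+CD25+GITR+ cells from the lymph nodes draining the tumour, 14 days after 300000 tumour cells had been placed under the skin. There were 6 libraries, 3 from wild-type (WT) mice and 3 from mice lacking Il33 (KO), the gene of the cytokine interleukin-33. The comparison of the 2 genotypes asked how chromatin accessibility of tumour-exposed Tregs differed without Il33. The WT libraries held 12.9 to 15.2 M tags (M, mega) after removal of duplicates (mean 13.7 ± 1.29 M, SD, n = 3), and the KO libraries 4.72 to 10.3 M (7.75 ± 2.82 M, n = 3), so every KO library was shallower than every WT library. Duplicate tags made up 14.2% ± 0.447 of the WT and 8.79% ± 0.368 of the KO tags (SD, n = 3 each). Peak heights, folds and significance values are the authors' own per-peak values and were not tested between genotypes. The labels do not state that replicates came from separate mice, so permutation p-values measure only the spread between these libraries, which may be technical. The p-values of tests on gene lists and single chromosomes have regions as units and do not measure that spread.

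At Il33 itself (chromosome 19, 29925113 to 29960718, mm10) each of the 6 libraries had 1 peak, in a region inside the gene at 29948010 to 29948768 that was called in all 3 WT and all 3 KO libraries. The sources used here do not give the position of the deleted part of Il33, so this peak does not check the genotype labels. At Il1rl1, which encodes ST2, the receptor of interleukin-33, the WT lists held 11.3 ± 1.53 peaks in or within 10 kb of the gene (chromosome 1, 40404864 to 40465418) and the KO lists 6.67 ± 1.53 (SD, n = 3 each). Of the 13 regions called there in any library, 10 were called in all 3 WT libraries. Of these 10, 4 were called in all 3 KO libraries, 5 in some of them, and 1, inside the gene at 40436927 to 40437311, in none. That region was weak, at within-list percentile 13.4, and was no longer WT-only when all lists were reduced to equal length. At Foxp3, the gene of the transcription factor that defines the Treg lineage (chromosome X, 7579676 to 7595243), the 4 regions called in all 3 WT libraries were also called in all 3 KO libraries. Another 2 regions at Foxp3 were called in some WT and no KO libraries. The WT lists held 6 ± 0 and the KO lists 4.67 ± 0.577 peaks there (SD, n = 3 each). At Ifng, which encodes interferon gamma (chromosome 10, 118441046 to 118445894), 1 region was called in all 6 libraries, and 2 others were called in some WT and no KO libraries.

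**Figure D1:**
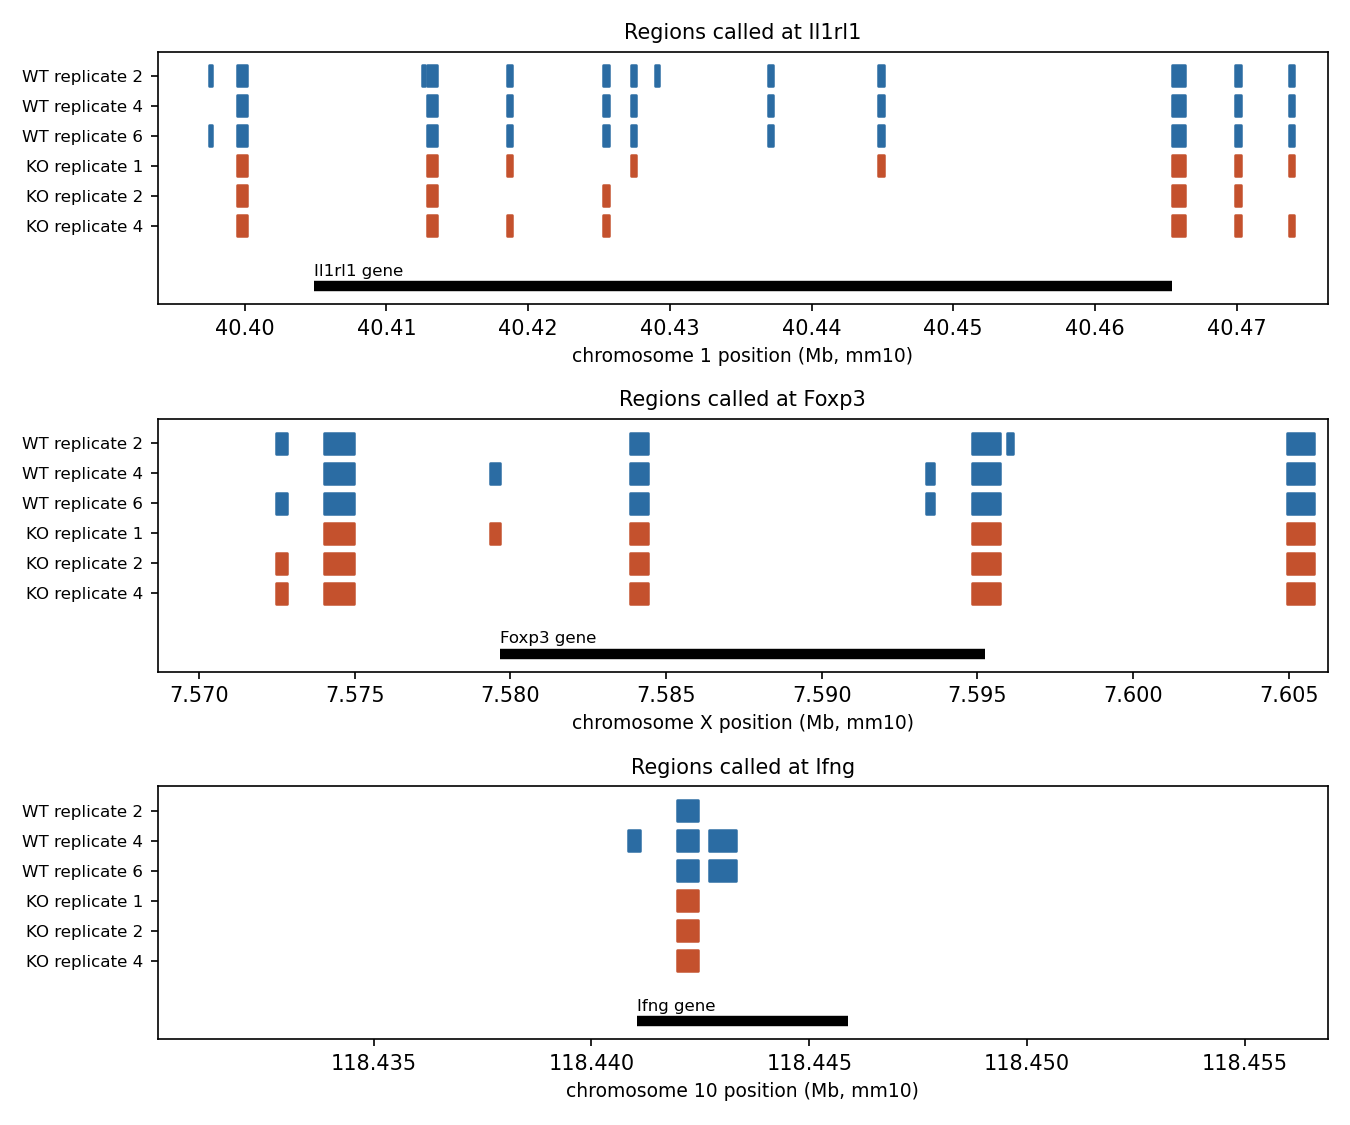
Regions called at Il1rl1, Foxp3 and Ifng along the chromosome (x axis, Mb, mm10), with 1 row per library (WT blue, KO red); each block is a merged region in which that library had a peak, and the black bar is the gene. The 4 Foxp3 regions found in every WT library recur in every KO library, while 1 weak Il1rl1 region (percentile 13.4) is present in the 3 WT and no KO libraries.

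Among other Treg genes, Ctla4, an inhibitory receptor, had 8.33 ± 0.577 peaks in WT and 6.67 ± 0.577 in KO lists. Il2ra, which encodes CD25, had 9.67 ± 0.577 and 7.67 ± 1.15, Tnfrsf18, which encodes GITR, 5.67 ± 0.577 and 5.33 ± 1.53, and Ikzf2, which encodes Helios, 23.3 ± 2.89 and 14.7 ± 2.08. Ccr7, whose product guides lymphocytes into lymph nodes, had 7 ± 1 against 4 ± 0 peaks. The transcription factor gene Gata3 had 7.33 ± 0.577 and 6.67 ± 0.577 peaks, Irf4 6.67 ± 0.577 and 6.33 ± 1.15, and Batf 5.33 ± 0.577 and 4.33 ± 1.15. Tbx21, the T-bet gene of Th1 cells, had 3 peaks in each of the 6 libraries, and the NF-kB subunit genes Rel and Nfkb1 had 4.33 ± 0.577 against 5 ± 1 and 15 ± 1.73 against 10.7 ± 1.53. The control gene Actb had 3.33 ± 0.577 in both groups (SD, n = 3 each throughout). Most of these differences shrank or turned round with the 37266 most significant peaks of each list, where 5 of the 17 genes chosen in advance had fewer and 8 had more peaks in KO. Il1rl1 then had 6.33 ± 1.53 peaks in WT and 6 ± 1 in KO, Ikzf2 14 ± 0 and 13.3 ± 1.15, and Ccr7 4 ± 1.73 and 3.33 ± 0.577. Irf4 had 4.33 ± 0.577 and 6.33 ± 1.15, Tnfrsf18 4.33 ± 0.577 and 5.33 ± 1.53, and Batf 4 ± 1 and 4.33 ± 1.15. Per 10000 peaks of the full lists, Ccr7 was still lower in every KO library (mean 0.984 against 1.30, two-sided exact permutation p = 0.1, the smallest possible).

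Across the genome, Tregs without Il33 yielded shorter peak lists. The WT lists held 54009 ± 1685 peaks and the KO lists 40804 ± 3068 (SD, n = 3 each), a KO to WT ratio of 0.756. Peaks covered 30.7 ± 0.983 Mb in WT and 21.0 ± 2.51 Mb in KO libraries. The share of peaks on chromosome X was 2.25% ± 0.0328 in WT and 2.14% ± 0.0238 in KO, that on chromosome 19, which carries Il33, was 3.12% ± 0.0225 and 3.16% ± 0.0513, and chromosome Y held 9, 8 and 9 peaks in the WT lists and 0 in each KO list. The groups did not overlap in number of peaks, covered length or the chromosome X share, each with p = 0.1 by a two-sided exact permutation test with n = 3 against 3, the smallest p this design allows. Depth separated the genotypes in the same way, and no library of one genotype reached the depth of the other, so depth and genotype cannot be told apart in these counts.

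**Figure D2:**
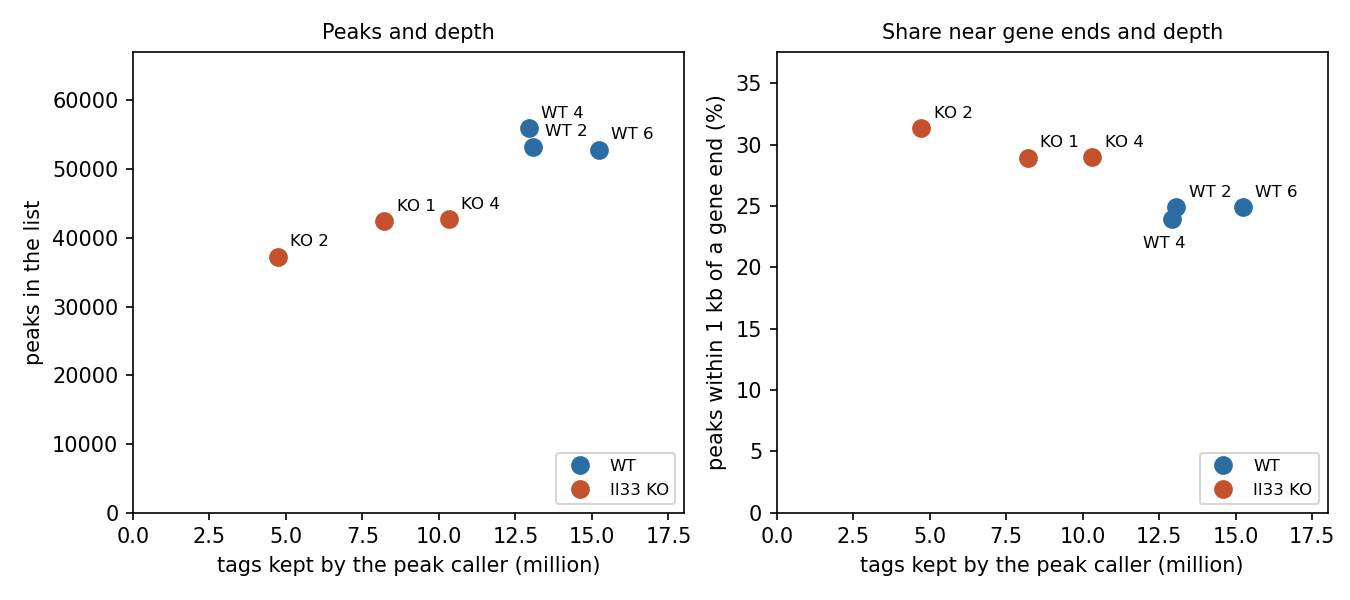
Peaks per list (left, count) and share of peaks within 1 kb of a protein-coding gene end (right, percent) against the tags kept by the peak caller (x axis, M) for the 3 WT (blue) and 3 KO (red) libraries, numbered by replicate. The KO libraries lie between 4.72 and 10.3 M tags and the WT libraries between 12.9 and 15.2 M, and the KO lists hold fewer peaks and a larger share near gene ends.

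The accessible regions of both genotypes were largely the same places. The 6 lists merged into 64817 regions, of which 29419 (45.4%) were called in all 6 libraries. Of the 29731 regions called in all 3 KO libraries, 99.0% were also called in all 3 WT libraries, while 67.6% of the 43512 regions called in all 3 WT libraries were called in all 3 KO libraries. The shared fraction of bases between lists (Jaccard index) averaged 0.716 among the WT pairs, 0.633 among the KO pairs and 0.594 between genotypes. Lists of one genotype resembled each other more on average than lists of different genotypes, by 0.080. Single pairs overlapped, as KO replicate 2 shared less with KO replicate 4 (0.614) than WT replicate 6 did (0.637). The gap was 0.051 in equal-length lists and 0.151 with a stricter threshold. In the lists as deposited, none of the 9 other ways to split the 6 libraries gave as large a gap (two-sided exact permutation p = 0.1, n = 3 against 3, the smallest this design allows). The genotype split is also the one that separates the deeper from the shallower libraries. Depth and genotype therefore cannot be told apart in this gap.

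WT-only regions, called in all 3 WT and in none of the KO libraries, numbered 3022, which is 6.95% of the regions called in all 3 WT libraries. They lay in or within 10 kb of 2306 protein-coding genes. Among WT-only regions within 10 kb of a protein-coding gene, the one ranked highest by within-list significance lay at the end of chromosome Y (90739434 to 90740602), 2.13 kb from the predicted gene Gm52481. It was followed by regions near Cndp2, a dipeptidase gene (chromosome 18, 84688377 to 84688668), inside Nceh1, a cholesteryl ester hydrolase gene (chromosome 3, 27209589 to 27210136), and inside Osbpl9, an oxysterol-binding protein gene (chromosome 4, 109147444 to 109148091). The next were near the predicted gene Gm38564 (chromosome 13), inside Pdzd2 (chromosome 15), near the end of Mid1 (chromosome X, 169993620 to 169994868) and near Fam207a (chromosome 10). Most WT-only regions were weak peaks: their median within-list percentile was 22.6, against 71.8 for regions called in all 6 libraries and 17.4 for regions called in exactly 3 libraries in another pattern. Of the 3022, 50 (1.65%) lay above the middle of the lists, against 0.113% of the latter.

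KO-only regions, called in all 3 KO and no WT libraries, numbered 12 (257 with 200 bp windows around peak centres, where WT-only regions numbered 3031), and 10 of them lay in or within 10 kb of a protein-coding gene. The 2 strongest were 4.43 kb from Pdzd8, which encodes a protein of endoplasmic reticulum contact sites (chromosome 19, 59350207 to 59351130), at within-list percentile 75.5, and 9.19 kb from the zinc finger gene Zfp791 (chromosome 8, 85132289 to 85132826), at 64.5. The other 6 of the 8 strongest near a gene ranked between percentiles 6.10 and 24.6. They lay near Lrtm2 (inside the neighbouring gene Cacna2d4), near Agmat, and inside Rabgap1l, Cnksr3, Nav2 and Mllt3. The 9 other splits of the 6 libraries into 3 and 3 gave 109 to 351 one-sided regions on their larger side and 14 to 84 on their smaller side.

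The asymmetry depended on list length and on how peaks were merged. When each list was reduced to its 37266 most significant peaks, the length of the shortest list, 470 regions were WT-only and 202 KO-only. The 672 together exceeded the 281 to 344 of the 9 other splits. Only the split by genotype parts the deeper from the shallower libraries. Equal length does not make depth equal, so depth and genotype cannot be told apart in this excess either. All 8 of the WT-only regions named above stayed WT-only in these shorter lists, and 5 with a stricter threshold, which lost those at Osbpl9, Gm38564 and Mid1. A region absent from a full list cannot enter its shortened form, so for strong peaks staying WT-only was largely given. Of the 8 KO-only regions, those near Pdzd8, Zfp791 and Lrtm2 stayed KO-only in the shorter lists and those near Pdzd8 and Zfp791 with the stricter threshold. Windows around peak centres lost the one near Pdzd8. Of the 202 KO-only regions, 98.0% had been called in at least 1 full WT list, whereas 40.9% of the 470 WT-only regions had been called in at least 1 full KO list. Presence calls in 3 against 3 libraries cannot give a p under 0.1 for any single region, and leaving out 1 library, which loosens the criterion, gave 3930 to 4909 WT-only and 21 to 68 KO-only regions.

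**Figure D3:**
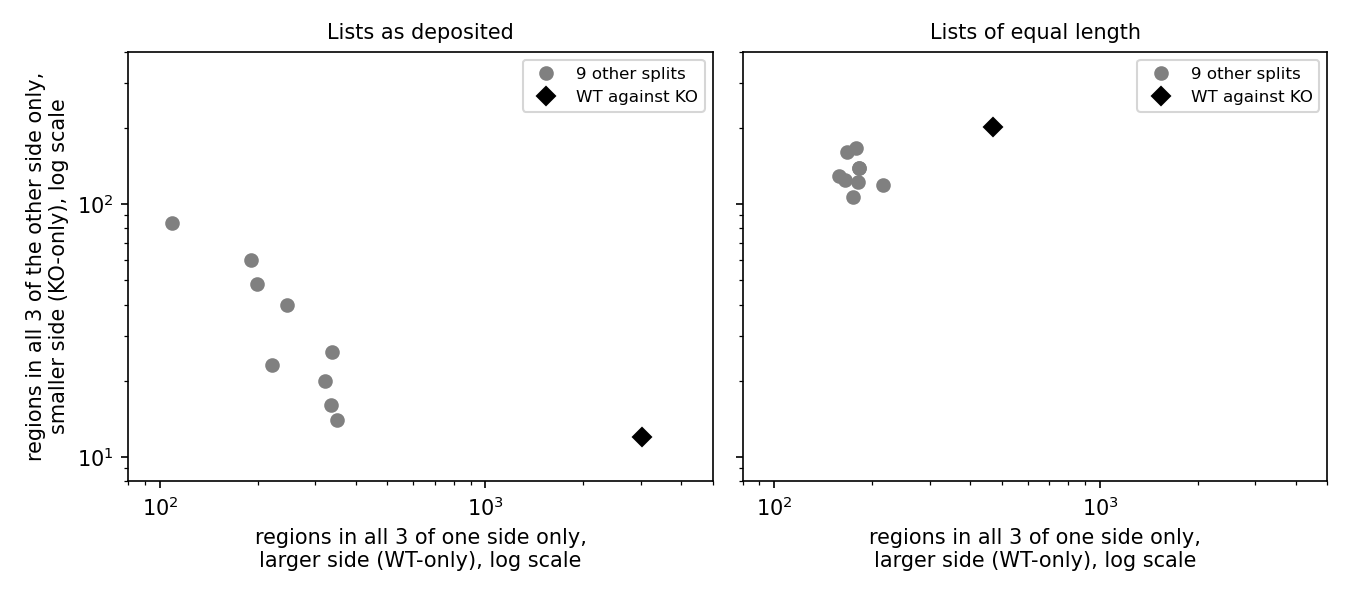
Regions called in all 3 libraries of one side and none of the other, for the split by genotype (diamond) and the 9 other splits of the 6 libraries into 3 and 3 (grey), with the larger side on the x axis and the smaller on the y axis (log scales, counts). As deposited the genotype split has 3022 WT-only and 12 KO-only regions, and with equal-length lists 470 and 202.

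Each of the 15 gene lists, housekeeping genes and markers of other cells included, had at least 1 WT-only region, and the 12 KO-only regions were too few to compare lists. In equal-length lists 9 WT-only and 7 KO-only regions lay at list genes, the latter at Foxp1, Bach2, S1pr1, Foxo1, Tnip1, Stat4 and Irf4. All 7 had been called in full WT lists, the one at Stat4 in 2 and the others in 3, so they became KO-only by the shortening. In the full lists the naive and lymph node homing list had the most WT-only regions, 14 at 9 of its 14 genes. From regions of like percentile 16.2 were expected, a test chosen after the data were seen. The 14 were led by a region at the transcription factor gene Klf2 (chromosome 8, 72321994 to 72322972) and included regions at Lef1 and Ccr7. Effector or tissue Treg genes had 8 regions at 7 of 19 genes, led by the chemokine receptor gene Ccr8 (chromosome 9, 120098361 to 120099020), Il1r2, which encodes the decoy receptor of interleukin-1, Tnfrsf8 and Itgb8. Treg core genes had 7 regions (7.25 expected) at 4 of 25 genes, Itgae, Nrp1, Capg and Ikzf2, and the NF-kB pathway had 5 (7.72 expected) at 4 of 32 genes, Nfkb1 (chromosome 3, 135630978 to 135631424), Tnip1, Tnfaip3 and Nfkbie. Th1 genes had 5 regions, at Stat4, Il12rb1 and Ccl4, and T cell activation genes 3, at Nfatc1, Cd44 and Fos.

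Fewer WT-only regions lay at the other lists, with 2 each at Tfh genes (Tox and Cxcr5), Th17 genes (Ccr6 among them) and interferon response genes (Ifit2 and Rsad2), and 1 each at the Th2 list (Ccr3) and the housekeeping control list (Eef1a1). Markers of cells other than Tregs had WT-only regions too, with 2 at B cell markers (Ebf1 among them), 2 at myeloid markers (Flt3 and Cebpb), 1 at CD8 T and NK markers (Klrb1c) and 1 at melanoma markers (Gpnmb). None of the 15 lists was over- or under-represented in either direction against the 2644 regions called in exactly 3 libraries in another pattern (Fisher's exact test, two-sided, 30 tests, lowest Benjamini-Hochberg adjusted p = 1). No unadjusted p was under 0.05. Effector or tissue Treg genes held 0.265% of WT-only and 0.0756% of those other regions (8 of 3022 and 2 of 2644, exact p = 0.117). In equal-length lists they held 0 of 470 and 0.463% of 2808. In the full lists 7.37 of the 8 were expected from regions of like percentile. In equal-length lists B cell markers held 3 of 470 WT-only regions (Pax5 and Ebf1 among them) and 0 of 2808 others (exact p = 0.00293, adjusted p = 0.0879). Of the 36 strongest WT-only regions taken for the lists, 6 stayed WT-only in equal-length lists (Ebf1, Ifit2, Nfkb1, Klf2 and Tox among them) and 1, at Ifit2, with a stricter threshold. Regions, not libraries, are the units of these tests.

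The share of each list's peaks that fell at a gene list was higher in every KO than in every WT library for 4 lists and lower for 1. Th2 genes took 0.0718% ± 0.00317 of KO and 0.0580% ± 0.00274 of WT peaks, and the NF-kB pathway 0.342% ± 0.0201 and 0.312% ± 0.00678. T cell activation genes took 0.232% ± 0.00602 and 0.206% ± 0.00468, and the housekeeping control genes 0.144% ± 0.00569 and 0.117% ± 0.00685, a ratio of 1.23 like the 1.24 of the Th2 list. B cell markers took 0.0545% ± 0.00542 in KO and 0.0605% ± 0.00177 in WT (SD, n = 3 each). The other 10 lists overlapped between the groups, with KO to WT ratios of 1.02 for Treg core and for effector or tissue Treg genes, 0.970 for Th1, 0.988 for Th17, 1.04 for Tfh, 0.949 for naive and homing, and 1.08 for interferon response genes. The ratios were 0.855 for CD8 T and NK, 1.02 for myeloid and 1.03 for melanoma markers. Chance alone separates 10% of lists with 3 against 3 libraries, and each of the 5 separated lists had p = 0.1 (exact permutation, two-sided, the smallest possible) and an adjusted p of 0.3 over the 15 lists. In equal-length lists 2 lists were separated, both lower in KO: Treg core genes with 0.371% ± 0.00310 of KO and 0.383% ± 0.00675 of WT peaks, and B cell markers with 0.0537% ± 0.00465 and 0.0653% ± 0.00410.

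**Figure D4:**
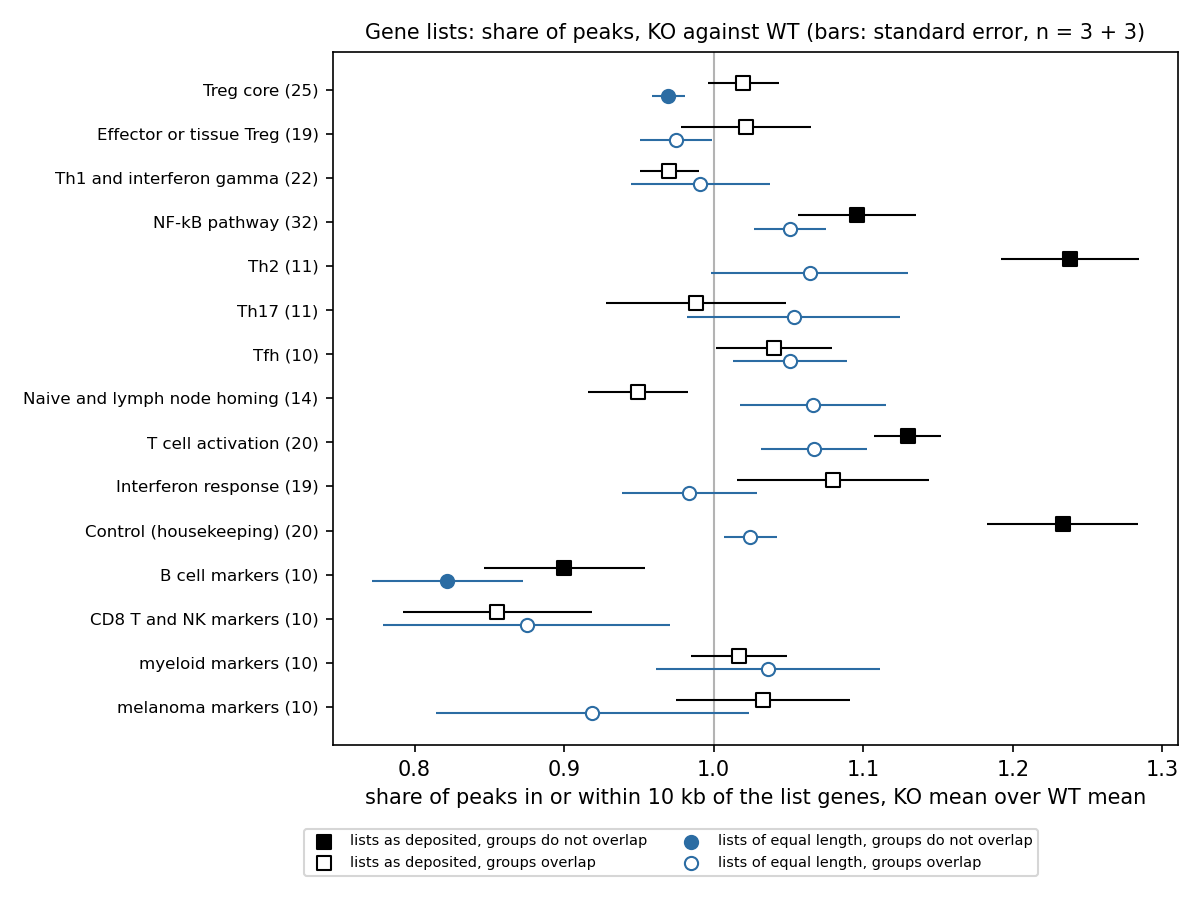
Share of peaks in or within 10 kb of the genes of each list, as the KO mean over the WT mean (x axis, ratio), with the number of matched genes in brackets, squares for lists as deposited and circles for equal-length lists, filled where the 3 KO and 3 WT libraries do not overlap; bars are standard errors. As deposited, the Th2 (1.24) and housekeeping control (1.23) lists have the highest ratios, and in equal-length lists B cell markers have the lowest (0.822).

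Peaks near the ends of protein-coding genes, which include promoters, made up a larger part of the KO lists. Of the peaks, 29.7% ± 1.38 in KO and 24.6% ± 0.560 in WT libraries lay within 1 kb of a gene end (SD, n = 3 each), a difference of 5.16 percentage points. Peaks elsewhere in gene bodies made up 39.3% ± 0.807 in KO and 42.3% ± 0.267 in WT, and intergenic peaks 31.0% ± 0.569 and 33.1% ± 0.293. None of the 3 shares overlapped between genotypes (p = 0.1 each, two-sided exact permutation test, n = 3 against 3, the smallest possible). In equal-length lists the share near gene ends was 31.1% ± 0.183 in KO and 30.2% ± 0.0518 in WT, a difference of 0.945 percentage points in the same direction. The gene body share no longer separated the genotypes there and was slightly higher in KO, with 38.4% ± 0.0480 against 38.3% ± 0.141 (exact permutation p = 0.2). KO replicate 2, the shallowest library, had the highest share near gene ends in both settings (31.3%). Depth separated the genotypes as well, so depth and genotype cannot be told apart in these shares.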

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

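Equal-length lists left out by library and a strength-matched list test were chosen after seeing the data. Peak number, similarity and the share near gene ends kept their direction in every alternative run for them, all at exact permutation p = 0.1, the smallest possible, except the pairs, which had no test. The lists remained without a call in all 14 alternatives. WT-only regions numbered 470 and KO-only regions 202 in equal-length lists, where 2 gene lists were separated in share in place of 5. A stricter threshold, the median significance of all lists, gave 2 KO-only regions and 9 separated lists. Windows around peak centres gave 257 KO-only regions, and the nearest gene end 3 separated lists; for these 2 settings the cause was not tested. Leaving out 1 library loosens the criterion by construction. WT-only counts were then 3930 to 4909, above 1.5 times the full count without WT replicate 2 (4538) or 6 (4747) or KO replicate 1 (4810) or 4 (4909). KO-only counts were 21 without WT replicate 2 to 68 without KO replicate 2, above 1.5 times for each of the 6 libraries. In equal-length lists they were 805 to 956 and 336 to 524. Of the 17 genes named in advance, 12 moved by more than their spread in equal-length lists (5 then had fewer KO peaks), 10 with the stricter threshold (15) and 9 with gene ends only (8). Both genotypes share the replicate numbers 2 and 4, and the labels do not say whether these numbers pair the samples. Deviations of same-numbered libraries correlated at -0.0165 and -0.0335, which gave no sign of pairing but cannot exclude it. With a replicate block of these 2 pairs there were 6896 WT-only and 83 KO-only regions and 8 separated lists, a criterion looser by construction. Motif alternatives were not run. KO replicate 2 had the fewest tags.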

Other observations

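The tests of depth, other splits, sex at chromosome Y, and the single chromosomes were chosen only after the results were seen, as were the spreads used as margins in all tests, while the bounds for multi-copy sequence and B cells were written before their values. WT-only regions were more frequent on chromosome X than elsewhere. Of the 956 chromosome X regions called in all 3 WT libraries, 100 (10.5%) were WT-only, where 69.3 were expected from regions of like within-list percentile on other chromosomes (strength-matched odds ratio 1.70, exact conditional p = 6.20e-05, adjusted p = 0.00130 over 21 tests of chromosomes 1 to 19, X, and X without Mid1, with regions as units). Without the regions at Mid1 the count was 95 of 949 (odds ratio 1.61, exact test, adjusted p = 0.00433). Every KO library was shallower than every WT library, so depth and genotype cannot be told apart in this excess on chromosome X. No autosome passed: chromosome 19 had 105 of 1350 against 84.3 expected (odds ratio 1.33, exact test, adjusted p = 0.0683), chromosome 3 had fewer, 133 against 161 (odds ratio 0.775, same adjusted p), and chromosome 13, with the highest autosomal share (8.10%), 160 of 1975 against 152.

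In equal-length lists, 107 regions in the last part of chromosome 19, past 55 Mb, were called in at least 3 libraries. Of these, 6 were WT-only and 2 KO-only (7.48%, against 1.81% over all chromosomes). Fisher's exact test against the regions elsewhere gave p = 0.000751, with regions as units. The window was chosen after its regions were seen, so this p cannot decide whether the share is unusual. The 2 KO-only regions lay near Pdzd8 (59350207 to 59351130) and Emx2, a homeobox gene (59454230 to 59454528); the former was no longer KO-only in windows around peak centres, a setting with 257 KO-only regions. Within 10 Mb of Il33 the share was 2.54% of 276 regions (Fisher's exact p = 0.357). Genes of the naive and homing list had 4 of the 202 KO-only regions in equal-length lists, at Foxp1, Bach2, S1pr1 and Foxo1, against 15 of 2808 other regions (Fisher's exact p = 0.0344, adjusted p = 0.516), and each of the 4 had been called in all 3 full WT lists.

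WT-only regions outnumbered KO-only regions, 3022 to 12. The genotype split was the only 1 of the 10 splits with so many one-sided regions (highest other 351) or with the 672 of equal-length lists (highest other 344), while 10 of the 10 splits had at least 12 regions on their smaller side (highest other 84); 10 splits are too few for a share under 0.05. Lower depth of the KO libraries was tested by predicting, from height and background scaled to the target library, how many regions of a library pair would be lost from another list. Losses from KO lists of regions called in a WT pair were 1.39 times the expected ones (median of 9, range 1.31 to 1.48), which passed the bound set for depth, the highest ratio of 1.30 between libraries of one genotype (lowest 0.762), but by less than the SD of those ratios, 0.237. In the other direction losses were 0.602 times the expected ones, so the prediction misses both ways, depth cannot be told apart from a genotype difference, and the latter stays open as untested.

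The strongest WT-only region near a protein-coding gene belonged to a block of 7 at the end of chromosome Y (90739434 to 90812981), with 5 further WT-only regions among the 7 called in all WT libraries at Mid1, at the end of chromosome X. A difference in sex is argued against by 0 peaks in any of the 6 lists at the Y genes Kdm5d, Eif2s3y, Uty and Ddx3y, although their X partners Kdm5c, Eif2s3x, Kdm6a and Ddx3x each had a region called in all 6; this replaced a first test that did not decide, as 2 WT peaks on Y lay outside the block. For lower KO depth as the cause, 1.11 ± 0.881 of the 7 regions of the block were expected to be WT-only from other regions of like percentile. This SD treats the 7 neighbouring regions as independent. Of the regions like the least affected member of the block, 0.0920% were WT-only. The expected number was below the 7 seen, but the block was examined because it held the strongest WT-only region. These values therefore cannot exclude depth as its cause. The value of 1.11 also missed a bound of 1 first set for a test from height and depth, which gave 0.285, and the margin in SD was chosen after both. For multi-copy sequence that differs between the mice, the bound was a local background above the 95th percentile of WT peaks of like height. The median percentile of that background was 86.9 (upper quartile 90.7), which missed the bound. It was still above that of most such peaks, so the test cannot exclude such sequence in fewer copies. A sequence difference between the mice at the ends of X and Y, and an effect of the genotype on chromatin there, stay open as untested.

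B cell markers were the list with the lowest raw p in equal-length lists, where genes including Pax5 and Ebf1 had a WT-only region. B cells in the WT sorts are a candidate explanation, although the sort on CD4, CD25 and GITR would remove them. Of the 10 markers, 8 had a peak in every library, among them Cd79a with 6 peaks in each WT list and 6, 3 and 5 in the KO lists, and Ms4a1 had 0 in every list; no marker is in another list. A second B cell list of 22 genes, 18 with a peak in every library, had 0 of the 470 WT-only and 4 of 2808 other regions, an odds ratio of 0 (Fisher's exact p = 1). This met the bound written against B cells, an odds ratio of at most 1, but with 0.67 regions expected without any enrichment the counts are too few to decide, chance among the 30 list tests (Fisher's exact test, adjusted p = 0.0879) stays open too, and the second list took 0.153% of WT and 0.155% ± 0.0157 of KO peaks in equal-length lists.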
